A study of Homo sapiens with 64 samples.

How the data were processed

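Total RNA from NCI-H295R cells was made into poly(A)-selected, strand-marking libraries with a TruSeq mRNA kit on an automated system, per the labels' protocols, and 16 libraries were pooled and sequenced. The deposited values are whole-number counts of reads per gene, not normalized, 1 file for each of 4 lanes of each library (64 files). Reads were aligned with STAR 2.4.2a to hg19 and counted with HTSeq 0.6.1p1, and DESeq2 1.14.1 was also named, per the submitters' processing notes. The annotation, the counting mode and the strand setting are not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies such as those of ribosomal proteins, carry an uncertainty that cannot be sized here. The files listed 26364 genes and no mitochondrially encoded gene, so that list was not tested.

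The 4 lane files of a library were summed, because lanes differed by little more than sampling noise: the chi-square per degree of freedom over genes was 0.998 to 1.04 between lanes of the 16 libraries, and 8.11 to 36.7 between the 18 pairs of libraries of 1 group. Summed libraries held 20148231 to 43992833 gene counts. Reads in no gene came to 11.3 to 16.5% of a library, highest in the siRNA-2 library 11-1, ambiguous reads to 1.05 to 1.33% and reads with several alignments to 7.47 to 8.17%; these were left out of library sizes and tests. The 10 highest genes took 2.58 to 2.9% of counts. The NNT count ranged from 837 to 17150 per library, so counting error was small beside the spread between libraries.

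Groups were taken from the labels: NNT shRNA (4 libraries), scrambled shRNA (3), NNT siRNA-2 (3), NNT siRNA-3 (3) and scrambled siRNA (3). The labels speak of triplicates, while 4 libraries carry the NNT shRNA label. Nothing says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. What the title codes stand for is not given.

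All 16 libraries entered 1 fit with a term per group, with TMM scaling, edgeR's filter for low counts (minimum count 10), quasi-likelihood tests in edgeR 4.0.16 under R 4.3.3 and Benjamini-Hochberg adjustment over the 15201 genes left, with a threshold of 0.05. The biological coefficient of variation was 0.118 on 11 residual degrees of freedom. There were 6 comparisons: the shRNA, siRNA-2 and siRNA-3 knockdowns, each against its scrambled control, the mean of both siRNAs against theirs, siRNA-2 against siRNA-3, and the shRNA effect minus the mean siRNA effect. CPM were computed on TMM-scaled totals. Standard errors came from the fold change and its F statistic. For 34 gene lists, camera in limma 3.58.1 was run with a preset correlation of 0.01 on log2 CPM with a prior count of 2, and again with an estimated correlation, with which no list passed in any comparison.

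The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule took NNT everywhere; in the shRNA and mean siRNA comparisons the 5 highest and 5 lowest log2 fold changes, and in the others 3 and 3, among genes past the threshold with an average log2 CPM of at least 3 and, except for the last comparison, every knockdown library on the same side of every control; 6 steroidogenic genes; the 2 members with the smallest p in each of 8 lists; and 3 genes each way in overlaps. Genes outside it are said to have been chosen after their values were seen. The result of 1 gene that the rule took is not reported.

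The shRNA title codes paired the libraries weakly at most. Deviations from the group means correlated by 0.141, 0.213 and 0.133 between libraries of 1 code, and by -0.181 to 0.156 between other pairs. The highest of the other pairs, NNT shRNA 2-3 with scrambled 24-2, lay above 0.141 and 0.133. Of the siRNA codes, 23-5 and 30-11 paired a siRNA-3 with a scrambled library (0.361 and 0.367), 11-1 and 16-1 did not (-0.019 and 0.014), and other pairs gave -0.318 to 0.17. Values from a fit with the code as a block are therefore given beside main results whose call, direction or count it changed, and not for each gene or list. The codes 11-12 (siRNA-2) and 2-3 (NNT shRNA) occur in 1 library each. A block term fits such a library exactly, so the block fit in effect leaves these libraries out.

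Alternatives were DESeq2's scaling, no low-count filter, a stricter filter (5 CPM in 3 libraries), only the groups compared, the title code as a block, robust dispersion, lane 1 only, each lane file as a library, DESeq2 1.42.0, the estimated correlation, and leaving out each library. On simulated counts with 200 changed genes, edgeR recovered 76.1% of 2-fold changes for the shRNA comparison, 76.6% for siRNA-2, 88.1% for siRNA-3, 88.1% for the mean of both, 76.1% between siRNAs and 61.2% for the difference of effects. Recovery of 1.5-fold changes ran from 31.3% for the difference of effects to 59.7% for the shRNA. Unchanged genes called ran from 1 for the difference of effects to 12 for the mean of both siRNAs. The simulation gave all groups the same spread per gene, which the real groups need not have. These shares therefore need not hold for the real comparisons. A list shifted 1.5-fold ranked 1 of 33 in camera, with 0 others called.

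For sequence motifs, 3' untranslated regions came from GENCODE transcripts on GRCh38, a later build than that of the counts, so they stand for those genes only by name. Of 12289 genes with an average log2 CPM over 1, 10901 (88.7%) had a region of at least 50 nt. Each of all 7-base words (7-mers) found in at least 50 genes was regressed, allowing for length and GC content, against signed z values of 4 contrasts: each of the 3 siRNA groups against the mean of the other 2, and the shRNA comparison, in Python 3.11.15 with numpy 2.4.6. A 7-mer planted in permuted values was found first (t = -8.6).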

Results

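The series measured messenger RNA in NCI-H295R cells, a human adrenocortical carcinoma line that makes steroid hormones, after knockdown of NNT. NNT encodes nicotinamide nucleotide transhydrogenase, an enzyme of the inner mitochondrial membrane that produces NADPH, and the series title names it as a treatment target in this cancer. Knockdown was made either with an shRNA (4 libraries, against 3 with a scrambled shRNA) or with 1 of 2 siRNAs, called siRNA-2 and siRNA-3 here as in the labels (3 libraries each, against 3 with a scrambled siRNA). The siRNA cells were harvested 72 h after transfection. The 16 libraries held between 20148231 and 43992833 gene counts each, and 17567 to 18571 genes had a count. Libraries are named by their group and the code in their title, such as 18-3.

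NNT was measured first in each library, because it checks the labels. NNT lies on chromosome 5 from 43602692 to 43707405 (plus strand, GRCh38), and its longest coding transcript has 22 exons. With the scrambled shRNA it stood at 371 ± 49.9 CPM (counts scaled to the library total; SD, n = 3), and with the NNT shRNA at 31.8 ± 2.95 CPM (SD, n = 4), each of the 4 libraries lying below each control. The log2 fold change was -3.54 (SE 0.32), an 11.7-fold lower level with an adjusted p of 2.36e-05 in edgeR's quasi-likelihood test, the source of each gene's adjusted p in this report. With the scrambled siRNA it stood at 337 ± 35.7 CPM and with siRNA-3 at 38.6 ± 8.28 CPM (SD, n = 3 each), a log2 fold change of -3.13 (SE 0.35, adjusted p = 0.000172). With siRNA-2 it stood at 157 ± 95.2 CPM (SD, n = 3). The single siRNA-2 libraries read 233 CPM (11-12), 187 CPM (16-1) and 49.9 CPM (11-1), all below the lowest scrambled siRNA library at 297 CPM. The siRNA-2 log2 fold change of -1.11 (SE 0.32) had an adjusted p of 0.0777 over all genes and did not pass. Its unadjusted p in the same test was 0.00306. It passed with the title code as a block (-1.561, adjusted p = 0.00913) and with no low-count filter (-1.11, adjusted p = 0.0235). The block in effect leaves out library 11-12, whose code no other library has, and without that library the log2 fold change was -1.51. Without library 11-1 it was -0.68. NNT was higher with siRNA-2 than with siRNA-3 by 2.02 on the log2 scale (SE 0.34, adjusted p = 0.00111), and by 1.176 (SE 0.262, adjusted p = 0.00927) with the title code as a block.

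**Figure D1:**
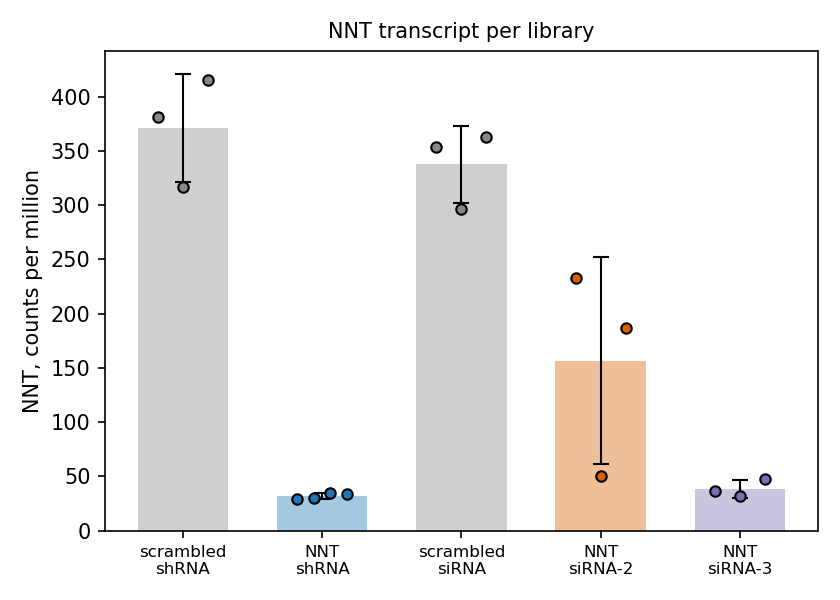
NNT in CPM (vertical axis) in each of the 16 libraries, by group. Bars are group means, error bars 1 SD and points single libraries; the 4 shRNA knockdown libraries sit between 28.7 and 34.6 CPM, the 3 siRNA-3 libraries between 31.8 and 47.8 CPM, and the siRNA-2 libraries spread from 49.9 to 233 CPM.

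The shRNA comparison asked which transcripts differ in cells that carry an NNT shRNA. Of 15201 genes tested, 3 passed. NNT fell by 3.54 on the log2 scale. PEX5L fell by 3.50 (SE 0.54, adjusted p = 0.0314), from 0.643 to 0.0522 CPM, and PAG1, an adaptor protein of the plasma membrane, rose by 1.90 (SE 0.31, adjusted p = 0.0435), from 0.259 to 0.969 CPM. PEX5L and PAG1 were both under 1 CPM and were chosen after their values were seen. Of all genes tested, 217 had an unadjusted p under 0.05 in edgeR's test, a smaller share than the 0.05 that unchanged genes give on average. With a spread shared by all 16 libraries, the test may thus be too strict here. Fitted on the shRNA libraries alone, 2 genes passed, and NNT had an adjusted p of 1.48e-09. PEX5L stood at 0.0763 CPM with siRNA-2, 0.0299 CPM with siRNA-3 and 0.0788 CPM with the scrambled siRNA. The scrambled shRNA group was thus the high one, and the NNT shRNA level lay among those of the siRNA groups, though the systems differ in other ways too. Steroidogenic genes gave no call: STAR, the cholesterol carrier that starts steroid synthesis, stood at 394 ± 35.3 CPM with the NNT shRNA (SD, n = 4) and 376 ± 66.6 CPM with the scrambled shRNA (SD, n = 3), a log2 fold change of 0.06 (SE 0.15). The log2 fold changes of the steroid enzymes CYP11A1, HSD3B2, CYP17A1 and CYP21A2 were 0.10, 0.37, -0.17 and 0.29, with SEs of 0.11, 0.44, 0.24 and 0.21. With the title code as a block they were 0.2, 0.644, 0.081 and 0.465, with SEs of 0.08, 0.255, 0.191 and 0.161, and none passed; without the scrambled library 24-2 STAR was -0.052, and without the scrambled library 19-2 CYP17A1 was 0.254. CYP11B1 was too low to test, at 0.0947 CPM with the NNT shRNA and 0.133 CPM with the scrambled one.

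Over all the fixed gene lists, edgeR called 0 of 812 tested members in the shRNA comparison, with 8 at an unadjusted p under 0.05 and 0 called by DESeq2, and 0 when adjusted over the list alone. The 2 NRF2 targets, antioxidant genes, with the smallest p were AKR1B10 (log2 fold change -0.79, SE 0.47) and ME1 (-0.14, SE 0.10), and for complex I of the respiratory chain they were NDUFA3 (0.26, SE 0.18) and NDUFS1 (0.10, SE 0.07). In the cell cycle lists, RRM2 (0.19, SE 0.11), CCNA2 (0.18, SE 0.12) and KIF11 (0.14, SE 0.11) were among the genes with the smallest p; with the title code as a block they were 0.029, 0.026 and -0.01. The highest of the 7 shRNA libraries for all 3 was the NNT shRNA library 2-3, whose code no scrambled library shares. The block in effect leaves that library out, and without it KIF11 was -0.01. Chaperone genes gave HSPD1 (0.16, SE 0.08), BAG3 (0.15, SE 0.09), MANF (0.10, SE 0.09) and SDF2L1 (0.12, SE 0.12), and the RNA interference genes TNRC6C and TNRC6B stood at -0.25 (SE 0.12) and -0.20 (SE 0.16). The adjusted p of each of these genes was 1. As a list, the genes of the cytosolic ribosome ranked higher with the NNT shRNA in camera with a preset correlation (adjusted p = 0.0014), with a median log2 fold change of 0.04 over 79 genes, 64 of them above 0, led by RPL41 (0.31, SE 0.13) and RPS14 (0.17, SE 0.10). The list gave an adjusted p = 0.866 with an estimated correlation.

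PEX5L and PAG1 did not pass without any 1 of the 7 shRNA libraries, with adjusted p up to 0.278 and 1. NNT alone passed without the NNT shRNA library 18-3, 19-2, 2-3 or 24-2 or the scrambled library 18-3 or 24-2, and 2 genes passed without the scrambled library 19-2. With the title code as a block NNT alone passed, while the block gave 5 lists in place of 1 and kept the ribosome list (adjusted p = 0.00785). That list missed the threshold without the NNT shRNA library 19-2 (adjusted p = 0.126) and the scrambled libraries 18-3 (0.677) and 24-2 (0.358). The list count went from 0 without the scrambled library 18-3 to 9 without the scrambled library 19-2, and was 2, 3, 4 and 6 without the NNT shRNA libraries 18-3, 19-2, 2-3 and 24-2 and 2 without the scrambled library 24-2.

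With siRNA-2, 299 genes differed from the scrambled siRNA, 151 higher and 148 lower. CDKN1A, an inhibitor of the cell cycle, rose 3.42-fold (log2 fold change 1.77, SE 0.29, adjusted p = 0.0105), CHST2 by 2.14 (SE 0.48, adjusted p = 0.0317) and DKK2, a secreted modulator of Wnt signalling, by 1.61 (SE 0.29, adjusted p = 0.0154). TGFBR3, a co-receptor of the TGF-beta family, fell by 1.08 (SE 0.26, adjusted p = 0.042), SGMS2, a sphingomyelin synthase, by 1.07 (SE 0.20, adjusted p = 0.0206) and LCOR, a transcriptional co-regulator, by 0.97 (SE 0.17, adjusted p = 0.0147). Without library 11-1 the log2 fold changes were 1.08 for CDKN1A (2.11-fold), 1.25 for CHST2 and -0.71 for TGFBR3.

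The genes of the integrated stress response under ATF4, which act in amino acid supply, were the siRNA-2 list with the most calls. Of 32 tested, 10 rose and 0 fell, and 21 rose and 1 fell when adjusted over the list alone. Among them, chosen after their values were seen, CHAC1, which breaks down glutathione, rose 2.46-fold, GDF15, a secreted stress factor, 6.4-fold, DDIT3, a stress transcription factor, 2.29-fold and ASNS, asparagine synthetase, 1.52-fold. GDF15 was low, at 4.46 CPM with siRNA-2 and 0.677 CPM with the scrambled siRNA. Without library 11-1 GDF15 was 3.07-fold higher, DDIT3 1.55-fold, ASNS 1.31-fold and the Wnt gene BMP4 1.28-fold, each missing the threshold. The list median was a log2 fold change of 0.41 (camera adjusted p = 1.42e-09; adjusted p = 0.343 with an estimated correlation). Wnt pathway genes had a median of 0.29, with 2 of 21 called, BMP4 and DKK1, both higher, and 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00175; adjusted p = 0.329 with an estimated correlation). Ribosome biogenesis had a median of 0.11 with 1 call, TCOF1, up by 0.32 (camera adjusted p = 0.00657; adjusted p = 0.938 with an estimated correlation). Markers of chromaffin or neural cells also ranked higher, with 2 of 6 called (camera adjusted p = 0.00175, and adjusted p = 0.329 with an estimated correlation). Their summed level was 72.0 to 96.8 CPM in the siRNA-2 libraries, 44.7 to 54.1 CPM in the siRNA-3 libraries and 58.6 to 61.7 CPM in the scrambled siRNA libraries. Transcripts without a poly(A) tail, mostly of histone genes and fixed as a sign of RNA quality, summed to 295.5 to 321.1 CPM with siRNA-2, 206.7 to 350.4 CPM with siRNA-3 and 217.3 to 371.2 CPM with the scrambled siRNA. As a list they missed the threshold with siRNA-2 (camera adjusted p = 0.308) but ranked higher without the scrambled library 30-11 (0.00596) and with the title code as a block (0.00347).

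List members named for siRNA-2 were chosen after their values were seen. The siRNA-2 calls depended on single libraries: 619 genes passed without library 11-12, 40 without library 11-1, 2 without the scrambled library 16-1 and 5 without the scrambled library 23-5. With markers of other cells left aside, none of the 29 genes named or called as list members for siRNA-2 passed in those last 2 fits. Of the 29, 28 passed without library 11-12, 2 without library 11-1 (CDKN1A and TGFBR3), 22 without library 16-1 and 12 without the scrambled library 30-11. Refitted on the siRNA-2 and scrambled siRNA libraries alone, 1 gene passed, 490 passed with the title code as a block, and DESeq2 called 905. The list count of 4 became 7 without library 11-1 or without the scrambled library 23-5, and ribosome biogenesis missed the threshold without the scrambled library 16-1 (adjusted p = 0.0927), as did chromaffin or neural markers with the title code as a block (0.0556).

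With siRNA-3, 323 genes differed from the scrambled siRNA, 131 higher and 192 lower. SLC16A9, a transporter of the monocarboxylate family, rose by 1.46 (SE 0.16, adjusted p = 0.000172), ARRDC3, an arrestin-domain protein, by 1.32 (SE 0.16, adjusted p = 0.000539) and CYP17A1, the enzyme that leads to cortisol and androgens, by 1.15 (SE 0.26, adjusted p = 0.0271), from 175 ± 46.8 to 387 ± 43.8 CPM (SD, n = 3 each). After NNT itself, ANKFN1 fell by 1.67 (SE 0.26, adjusted p = 0.00278) and RNF11, a ubiquitin ligase, by 1.38 (SE 0.14, adjusted p = 0.000109).

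As lists, 13 passed with siRNA-3, 8 higher and 5 lower. Each had an adjusted p = 0.748 with an estimated correlation. Steroidogenesis ranked higher, with a median of 0.10 and CYP17A1 as the 1 call among 32 genes, or 5 when adjusted over the list alone (camera adjusted p = 0.0285). Cholesterol synthesis had a median of 0.25 and 1 call, MSMO1, up by 0.72, or 3 when adjusted over the list alone (camera adjusted p = 0.00401). The S phase list (median 0.12, camera adjusted p = 0.00401), with CCNE1 up by 0.93, and the G2 and M phase list (median 0.20, camera adjusted p = 0.00338) ranked higher. So did the cytosolic ribosome (0.08, camera adjusted p = 0.00401), the mitochondrial ribosome (0.06, camera adjusted p = 0.0285), ribosome biogenesis (0.09, camera adjusted p = 0.0428) and the ATF4 genes (0.17, camera adjusted p = 0.0206). In the last of these edgeR called 0 of 32 members, with 9 at an unadjusted p under 0.05 and 1 called by DESeq2. NRF2 targets ranked lower with a median of -0.15 over 29 genes (camera adjusted p = 0.00708). Glutathione genes had a median of -0.12 (camera adjusted p = 0.0443), interferon response genes -0.22 with IFI44L and IRF9 called lower (camera adjusted p = 0.0155), and Wnt pathway genes -0.25 with CCND1, APCDD1 and ISM1 called lower of 21 (camera adjusted p = 0.00401). CCND1 stood at 0.293 CPM with siRNA-3 and 0.743 CPM with the scrambled siRNA, and its log2 fold change with siRNA-2 was -1.17. In the 6 fits that left out 1 library CCND1 passed in 0, ISM1 in 1, APCDD1, IRF9 and MSMO1 in 2 and IFI44L in 3, and ISM1 went from -0.78 to -0.51 without library 23-5. List members named for siRNA-3 were chosen after their values were seen. Chromaffin or neural markers ranked lower too (camera adjusted p = 0.0159), at the summed levels given with siRNA-2.

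The siRNA-3 count was 69 without library 11-1, 192 without library 23-5, 530 without library 30-11, 100 without the scrambled library 16-1 and 77 without the scrambled library 23-5. NNT, SLC16A9, ARRDC3, ANKFN1, RNF11 and CCNE1 passed in each of those fits and without the scrambled library 30-11. Of 26 genes named or called as list members, 8, 11, 23, 9, 8 and 15 passed without the siRNA-3 libraries 11-1, 23-5 and 30-11 and the scrambled libraries 16-1, 23-5 and 30-11, and CYP17A1 passed in 2 of those 6 fits, with an adjusted p up to 0.122. Steroidogenesis missed the threshold without library 30-11 (adjusted p = 0.144) and the scrambled libraries 16-1 (0.0571) and 23-5 (0.148). The ATF4 genes missed it without library 23-5 (0.0745), the cytosolic ribosome without the scrambled library 23-5 (0.26), and chromaffin or neural markers without the scrambled library 23-5 (0.0514). The mitochondrial ribosome missed it without library 30-11 (0.285) and the scrambled libraries 16-1 (0.164) and 23-5 (0.211), and ribosome biogenesis without libraries 11-1 (0.108) and 30-11 (0.064) and the scrambled library 16-1 (0.201). Glutathione genes missed it without libraries 11-1 (0.106) and 30-11 (0.0697) and the scrambled libraries 16-1 (0.122) and 30-11 (0.169), and interferon response genes without library 23-5 (0.356) and the scrambled library 30-11 (0.0989). With the title code as a block, cholesterol synthesis (0.0565), glutathione genes (0.131), ATF4 genes (0.276) and ribosome biogenesis (0.304) missed it. The siRNA-3 and scrambled siRNA libraries alone gave 56 genes, and DESeq2 gave 859.

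**Figure D2:**
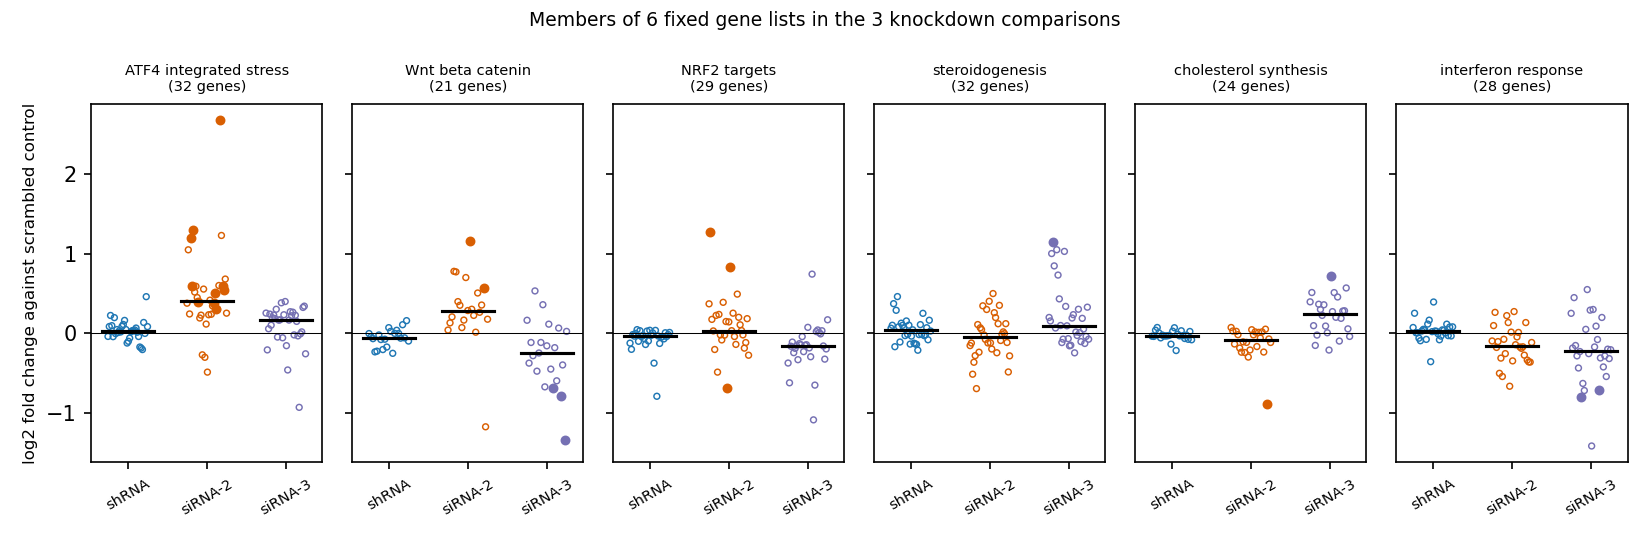
Log2 fold changes against the matching scrambled control (vertical axis) of the tested members of 6 fixed gene lists in the shRNA, siRNA-2 and siRNA-3 comparisons. Each point is 1 gene, filled where its adjusted p is under 0.05, and black bars are list medians; the Wnt pathway median is 0.29 with siRNA-2 and -0.25 with siRNA-3.

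The mean of both siRNAs against the scrambled siRNA gave 35 genes, 14 higher and 21 lower. TAPT1, a membrane protein, rose by 0.68 (SE 0.07, adjusted p = 0.000499), from 29.1 ± 2.10 CPM to 47.2 ± 1.07 with siRNA-2 and 46.1 ± 3.94 with siRNA-3 (SD, n = 3 each). BOD1 rose by 0.60, PDCD6, a calcium-binding protein, by 0.56, PPP2R1B, a phosphatase subunit, by 0.55 and EYA3 by 0.55, with adjusted p from 0.0135 to 0.0445. After NNT, which fell by 2.12 (SE 0.27, adjusted p = 0.00214), DTNA, dystrobrevin alpha, fell by 0.84 (SE 0.11, adjusted p = 0.00405), LOC100129550 by 0.76, IFI44L by 0.67 and MR1, an antigen-presenting molecule, by 0.58, with adjusted p up to 0.0481. In the steroid pathway, log2 fold changes were 0.02 for STAR, 0.02 for CYP11A1, 0.24 for HSD3B2, 0.39 for CYP17A1 and 0.28 for CYP21A2, with adjusted p of 0.48 or above. Without the scrambled library 23-5 STAR was -0.133, CYP11A1 -0.072 and HSD3B2 -0.08, and with the title code as a block STAR was -0.092. CYP11B1 was again too low to test.

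For the mean of both siRNAs 5 lists passed, each with an adjusted p = 0.976 with an estimated correlation. ATF4 genes had a median log2 fold change of 0.28, with 28 of 32 above 0 (camera adjusted p = 2.17e-08). edgeR called 0 of them, 16 had an unadjusted p under 0.05, DESeq2 called 3, and 7 rose when adjusted over the list alone, XPOT (0.43) and AARS (0.32) having the smallest p. Ribosome biogenesis (median 0.08, camera adjusted p = 0.00353), S phase (0.08, camera adjusted p = 0.0198) and G2 and M phase genes (0.10, camera adjusted p = 0.0204) ranked higher. Their leading members were TCOF1 (0.24) and NOP56 (0.26), CCNE1 (0.59) and MCM4 (0.23), and MKI67 (0.40) and ANLN (0.28), none past the threshold. Interferon response genes ranked lower, with a median of -0.18 and IFI44L called (camera adjusted p = 0.00741). The log2 fold changes of RPL15, RPL14, MRPL35, MRPS22, GGT1 and LAP3, from lists that did not pass, were 0.17, 0.16, 0.23, 0.20, -0.67 and -0.22.

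The count of 35 became 21 without the siRNA-2 library 11-1, 7 without the siRNA-3 library 11-1, 54 without the siRNA-3 library 30-11, 3 without the scrambled library 16-1, 2 without the scrambled library 23-5 and 55 without the scrambled library 30-11, and NNT and TAPT1 passed in all 9 fits without 1 library. Of 10 genes named as called, 8, 7, 4, 9 and 9 passed without the siRNA-2 libraries 11-1 and 16-1 and the siRNA-3 libraries 11-1, 23-5 and 30-11, and 2, 2 and 8 without the scrambled libraries 16-1, 23-5 and 30-11. It was 2 with only the siRNA groups fitted, 2 with the title code as a block (NNT and DTNA) and 287 with DESeq2, and the list count became 8 without the siRNA-2 library 11-1. G2 and M phase genes missed the threshold without the siRNA-2 library 11-12 (adjusted p = 0.198), the siRNA-3 libraries 11-1 (0.112) and 30-11 (0.151) and the scrambled libraries 16-1 (0.117) and 23-5 (0.195), and with the block (0.263). Interferon response genes missed it without the siRNA-3 library 23-5 (0.0901) and the scrambled library 30-11 (0.0891), and without the scrambled library 16-1 so did S phase genes (0.157) and ribosome biogenesis (0.0787).

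Whether the siRNAs against 1 target moved the same genes was asked directly. Across genes, which are not independent replicates, their log2 fold changes correlated with Pearson's r = 0.229 and Spearman's rho = 0.174. Unchanged groups simulated against the same 3 controls gave 0.525 and 0.474 over 100 draws, because the controls are shared. The covariance was 0.0244 against a simulated 0.0284 (SD 0.0011), a difference of -0.00398. Both siRNAs called 10 genes higher and 9 lower, where independent lists, without shared controls, would share 1.3 and 1.87. Another 5 went opposite ways, where 3.18 would. Simulated groups shared 0, which decides nothing here, since groups drawn unchanged give few calls to share. Without the scrambled library 16-1 or 23-5 both siRNAs called 1 gene higher and 0 lower, but siRNA-2 then called only 2 and 5 genes. Without the scrambled library 30-11 they shared 14 higher and 10 lower. The 3 shared controls are too few to split for a direct measure of their part in these overlaps. TAPT1 (0.70 and 0.66), GPR137C (0.69 and 0.62) and NRBF2 (0.61 and 0.66) led the genes higher with siRNA-2 and siRNA-3, and DTNA (-0.92 and -0.76), LOC100129550 (-0.73 and -0.79) and MR1 (-0.69 and -0.48) the genes lower with both. The correlation was 0.393 without the scrambled library 30-11 and 0.087 among genes of at least 5 CPM in 3 libraries.

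**Figure D3:**
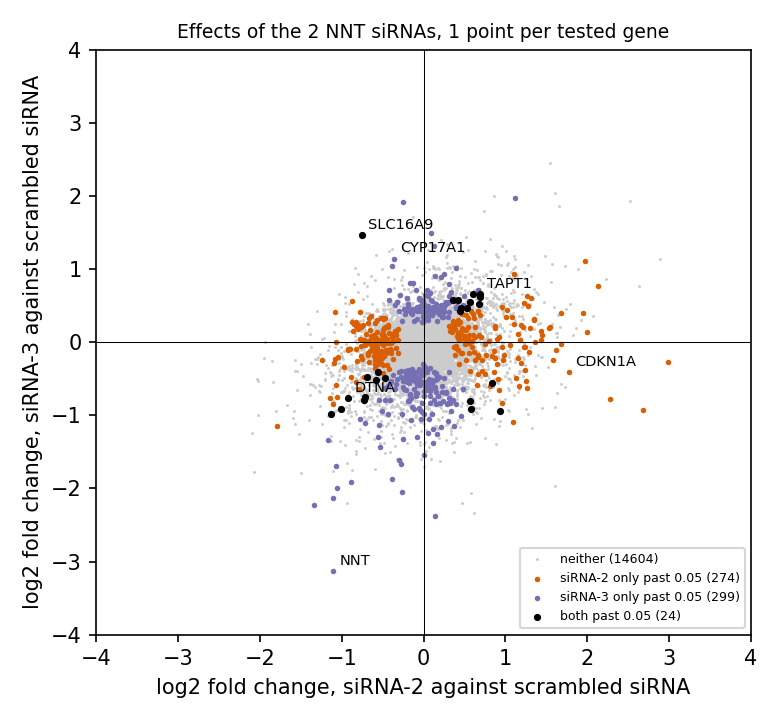
Log2 fold change of each tested gene with siRNA-2 (horizontal axis) and siRNA-3 (vertical axis) against the scrambled siRNA. Coloured points are genes past an adjusted p of 0.05 with siRNA-2 alone (274), siRNA-3 alone (299) or both (24).

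Compared with each other, the siRNAs differed in 2191 genes, 1119 higher and 1072 lower with siRNA-2. CDKN1A was higher with siRNA-2 by 2.18 (SE 0.30, adjusted p = 0.00026) and HMOX1, heme oxygenase, by 1.89 (SE 0.26, adjusted p = 0.000281). SLC16A9 was lower with siRNA-2 by a log2 difference of -2.21 (SE 0.17, adjusted p = 1.38e-06), as were CYP17A1 (-1.51, SE 0.26, adjusted p = 0.00145) and TGFBR3 (-1.49, SE 0.26, adjusted p = 0.00175). Of 21 Wnt pathway genes 12 were higher with siRNA-2 and 0 lower, 13 and 0 when adjusted over the list alone, among them AXIN2 (0.50), NKD1 (1.06) and NOTUM (1.37), all feedback targets of the pathway (camera adjusted p = 5.97e-06; adjusted p = 0.0951 with an estimated correlation). NOTUM was low, at 1.71 CPM with siRNA-2 and 0.649 CPM with siRNA-3. Of 24 cholesterol synthesis genes 6 were lower with siRNA-2, or 11 when adjusted over the list alone, INSIG1 by -1.45 and SQLE by -0.60 (camera adjusted p = 0.000423; adjusted p = 0.829 with an estimated correlation). Of 32 steroidogenic genes 6 were lower and 1 higher with siRNA-2, the same when adjusted over the list alone; those lower included HSD3B2 (-1.51), CYP21A2 (-1.13) and the ACTH receptor MC2R (-1.10), and the list as a whole did not pass camera (adjusted p = 0.139). ATF4 genes gave 12 higher and 2 lower, the same when adjusted over the list alone (camera adjusted p = 0.0046; adjusted p = 0.829 with an estimated correlation), and NRF2 targets 7 higher and 2 lower, or 9 and 2 when adjusted over the list alone (camera adjusted p = 0.0116; adjusted p = 0.829 with an estimated correlation). List members named here were chosen after their values were seen. Chromaffin or neural markers were higher with siRNA-2, with 4 of 6 called (camera adjusted p = 1e-04, and adjusted p = 0.0951 with an estimated correlation), at the summed levels of 72.0 to 96.8 against 44.7 to 54.1 CPM. Lower with siRNA-2 were complexes II to V of the respiratory chain (median -0.12, camera adjusted p = 0.0287; UQCRC2, COX4I1, COX7C and COX8A called), the cytosolic ribosome (-0.09, camera adjusted p = 0.0298; RPL23 and RPL34 called) and G2 and M phase genes (-0.12, camera adjusted p = 0.048; KIF23 called), each with an adjusted p = 0.829 with an estimated correlation. Of 11 transcripts without a poly(A) tail 10 were above 0 and 2 called higher with siRNA-2 (camera adjusted p = 0.0916). The count was 1091 without the siRNA-2 library 11-1, 1092 without the siRNA-3 library 11-1 and 530 with only those groups fitted, and CDKN1A, HMOX1, SLC16A9, CYP17A1 and TGFBR3 passed in each fit that left out 1 library. Without the siRNA-2 library 11-1, ATF4 genes (adjusted p = 0.126) and NRF2 targets (adjusted p = 0.12) missed the threshold as lists, and CDKN1A was 1.49 and NKD1 0.62; with the title code as a block TGFBR3 was -2.101. Complexes II to V missed it without the siRNA-2 libraries 11-12 (0.11) and 11-1 (0.126) and the siRNA-3 libraries 11-1 (0.0578) and 30-11 (0.117), the cytosolic ribosome without the same 4 (0.337, 0.158, 0.143 and 0.128), and G2 and M phase genes without the siRNA-2 libraries 11-1 (0.158) and 16-1 (0.152) and the siRNA-3 libraries 11-1 (0.23) and 30-11 (0.269). HSD3B2 passed in 1 of those 6 fits (adjusted p up to 0.162), MC2R in 3 (up to 0.0621) and NOTUM in 5 (up to 0.0532), and AXIN2, NKD1, INSIG1, SQLE and CYP21A2 in all 6. Without the siRNA-2 library 11-1 none of UQCRC2, COX4I1, COX7C, COX8A, RPL23, RPL34 and KIF23 passed.

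The last comparison asked whether the knockdown effect differed between the shRNA and the siRNAs. Their log2 fold changes correlated across genes with Pearson's r = 0.066 and Spearman's rho = 0.021, with no library in common, and NNT was the 1 gene called lower in both. The effect itself differed for 1 gene, TAPT1, whose shRNA log2 fold change of -0.03 lay 0.71 below the siRNA mean of 0.68 (difference -0.71, SE 0.11, adjusted p = 0.0412). Its levels were 43.6 ± 0.948 CPM with the NNT shRNA (SD, n = 4), 44.5 ± 0.886 CPM with the scrambled shRNA and 29.1 ± 2.10 CPM with the scrambled siRNA (SD, n = 3 each). With siRNA-2 and siRNA-3 it stood at 47.2 ± 1.07 and 46.1 ± 3.94 CPM (SD, n = 3 each). The scrambled siRNA group alone was low, so the difference rests on that control. The difference for NNT was -1.43 (SE 0.42, adjusted p = 0.783). Between the knockdown effects 4 lists differed, each with an adjusted p = 0.984 with an estimated correlation: ATF4 genes (median difference -0.26, camera adjusted p = 0.000149), ribosome biogenesis (-0.08, camera adjusted p = 0.00867), the endoplasmic reticulum unfolded protein response (0.12, camera adjusted p = 0.0174) and interferon response genes (0.22, camera adjusted p = 0.00867). TAPT1 passed without the siRNA-2 library 11-1 (2 genes) or the siRNA-3 library 30-11 (1 gene); without the scrambled siRNA library 30-11 2 other genes passed, and without any of the remaining 13 libraries edgeR called 0, against 907 genes at an unadjusted p under 0.05 and 11 called by DESeq2 with all libraries. With the title code as a block TAPT1 (-0.649, adjusted p = 0.21), ribosome biogenesis (adjusted p = 0.0704) and the unfolded protein response (adjusted p = 0.0572) missed the threshold. The list count was 2 without the siRNA-3 library 23-5 and 7 without the scrambled siRNA library 23-5. The unfolded protein response missed the threshold without the NNT shRNA library 18-3 (adjusted p = 0.0772), the siRNA-2 library 11-12 (0.0532), the siRNA-3 library 23-5 (0.0514) and the scrambled shRNA library 24-2 (0.0532). Interferon response genes missed it without the siRNA-3 library 23-5 (0.11) and the scrambled siRNA library 30-11 (0.0918), and ribosome biogenesis without the scrambled shRNA library 19-2 (0.348) and the scrambled siRNA library 16-1 (0.0983). Across genes, the correlation was 0.029 without the scrambled shRNA library 18-3 and 0.031 without the NNT shRNA library 24-2.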

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

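The motif tests for the siRNA difference, the share of genes moving as in the shRNA knockdown and the tests of the genes higher in the mean of both siRNAs were chosen only after the result was seen; the tests of library 11-1 and the regroupings of libraries were not.

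Between siRNA-2 and siRNA-3, 2191 genes differed by a test of the difference itself, with log2 differences of 2.02 for NNT (1.176 with the title code as a block), 2.18 for CDKN1A, 1.89 for HMOX1, -2.21 for SLC16A9, -1.51 for CYP17A1 and -1.49 for TGFBR3 (-2.101 with the block); the 10 splits of the 6 libraries are too few for a share under 0.05, the highest other giving 2. If the larger amount of NNT left with siRNA-2 were the cause, these genes should move in the shRNA knockdown as in siRNA-3 against siRNA-2. NNT was as low with the shRNA as with siRNA-3, but 47.8% of the genes moved so. That argues against NNT dose as the whole cause only if the shRNA cells show the response seen at 72 h. The labels give no time for the shRNA cells. A candidate explanation is that each siRNA also lowers transcripts matching its seed, the bases of a guide that pair with 3' untranslated regions: the 7-mers most tied to lower levels were CTTGTAA for siRNA-2 (t = -18.4) and CCAACTC for siRNA-3 (t = -13.0), against 4.8 as the largest absolute t in 20 permutations. The bound is not proof of a seed, since TATTTAT, tied to higher levels with siRNA-2, also passed it (t = 6.6), but the weakest t in genes not used to choose the 7-mer was -6.8, and these 7-mers occur in NNT, where 28.8% of all 7-mers do. Sites of the 2 leading 7-mers, ranked without the called genes, lay in 67.4% of the genes lower with siRNA-2 (19.3% of all searched) and 45.2% of those lower with siRNA-3 (15.9%), but in 45.1% of the genes lower with siRNA-2 than with siRNA-3 and 22.7% of those lower with siRNA-3 than with siRNA-2, so other effects stay open, and the siRNA sequences are not given in the sources used here.

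Genes higher in the mean of both siRNAs than with the scrambled siRNA, 14 in number, are the next pattern; not all were higher with each siRNA, ARRDC3 having log2 fold changes of 0.12 with siRNA-2 (adjusted p = 0.737) and 1.32 with siRNA-3. Loss of NNT as the cause predicts a rise in the shRNA knockdown too, but their median log2 fold change there was 0.002 (SE 0.022) with 7 of 14 above 0, against 0.516 with the siRNAs. That argues against it, again only if the shRNA cells, whose time is not given, show the response seen at 72 h. A seed effect of the scrambled siRNA, lowering them in the controls, is a candidate explanation tested in 4 versions, the later ones made after the first found a site of its leading 7-mer, GACGTAT, in 0 of the 14, which decides nothing because 0.188 were expected. The others found sites of the top 4 7-mers absent from NNT in 8 (57.1%, against 10.5% of all; exact one-sided Fisher p = 2.48e-05), of the 5 past the permuted bound when ranked without these 14 genes in 9 (64.3%, against 1207 of all 10901 genes searched; p = 2.9e-06), and of those 5 with TTTATTT, present in NNT, in 12 (85.7%, against 48.8%; p = 0.00502), as a seed effect predicts, though it stays a hypothesis found and tested on the same data. Of the pooled 7-mers, GACAGTA, in 871 of the genes searched, lacks the core GACGTA of the others, and TTTATTT matches neither. The pooled shares therefore do not tie these genes to a single seed. The median level of the 14 in the scrambled siRNA libraries relative to scrambled shRNA was -0.39 in log2, a comparison that also carries every other difference between the systems.

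Library 11-1 of siRNA-2 stood apart, at -50.7 on a second principal component holding 18.3% of the variance (-10.4 and -13.6 for the other siRNA-2 libraries), with NNT at 49.9 CPM and the largest share of reads in no gene (16.5%). A siRNA-3 library under a siRNA-2 label would carry the siRNA-3 motif, but its siRNA-3 slope was -0.009 (SE 0.012), against -0.118, -0.130 and -0.065 in the siRNA-3 libraries. Its siRNA-2 slope was -0.268 (SE 0.012), against -0.089 and -0.091 (SE 0.006 each) in the other siRNA-2 libraries, so a stronger siRNA-2 action, as from more siRNA taken up, may account for part of its distance. RNA quality was not excluded: transcripts without a poly(A) tail summed to 321.1 CPM in it and 295.5 and 297.5 CPM in the other siRNA-2 libraries.

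Library 30-11 of the scrambled siRNA, a control in each comparison with the scrambled siRNA, also stood apart, at 1 on the first principal component (22.1% of the variance; 14.2 and 15.3 for the other scrambled siRNA libraries) and 1 on the third (9.1%; -18.9 and -24.6), with transcripts without a poly(A) tail at 371.2 CPM (247.1 and 217.3). These were at 350.4 CPM in the siRNA-3 library of the same code (259.1 and 206.7 in the other siRNA-3 libraries), and without the scrambled library 30-11 the correlation between siRNAs was 0.393.

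TAPT1 was the 1 gene whose knockdown effect differed between shRNA and siRNAs by a test of the difference (-0.71). The difference rests on the scrambled siRNA group, at a mean of 29.1 CPM, against means of 43.6 to 47.2 CPM in the other groups. TAPT1 was also among the genes with a site of the pooled scrambled siRNA 7-mers in each version of that test but the first. In 8 of 100 splits of the libraries, the real one among them and the others drawn, at least 1 gene differed (highest other 79), so chance is not excluded. The 95% exact binomial interval of that share, 3.52 to 15.2%, counts the real split too and spans 5%, so the draw itself cannot place it. The drawn splits also mix siRNA-2 and siRNA-3 libraries, which differ from each other, so the share does not measure chance alone. Of lists, 4 differed in the same test, with median differences of -0.258 for ATF4 genes, 0.121 for the endoplasmic reticulum unfolded protein response, -0.082 for ribosome biogenesis and 0.216 for interferon response genes. As many lists came from 78 of the 100 splits, again with the real one counted (highest other 13), so chance is not excluded for them.

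Single NNT shRNA libraries lay far from the other 3 for 6 of 26 groups tested, where chance gives about 1 in 20. In library 2-3 CCNA2 stood at 270.3 CPM, KIF11 at 402.3, RRM2 at 509.2 and CYP11A1, the lowest of its group, at 248.5 CPM. In library 19-2 RPL41 stood at 499.6 CPM and NDUFA3 at 46.11 CPM.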

How the results depend on the processing

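No test in this part was chosen only after the result was seen, and the cause of a change was not tested unless given. Robust dispersion and DESeq2's scaling kept the gene count of all 6 comparisons within 1.5 times. With the title code as replicate block the shRNA count was 1 (5 lists), siRNA-2 490 and the mean of both siRNAs 2, and NNT with siRNA-2 passed (-1.56, adjusted p = 0.00913). In that fit siRNA-3 gave 454 genes and the siRNA difference 2794. The block in effect leaves out the siRNA-2 library 11-12 and the NNT shRNA library 2-3. The strict filter gave 1 gene for the shRNA and a correlation of 0.087 between siRNAs. No low-count filter gave 464 genes for siRNA-2, 85 for the mean and 0 for the difference of effects, and NNT with siRNA-2 passed (-1.11, adjusted p = 0.0235). Only the groups compared, with fewer libraries and a spread estimated from those groups alone, gave 1 gene for siRNA-2 and 56 for siRNA-3. It gave 2 for the mean and 530 between siRNAs, and NNT in the mean missed the threshold (-2.12, adjusted p = 0.113). For NNT with the shRNA the adjusted p went the other way, from 2.36e-05 to 1.48e-09. The main siRNA counts thus depend on the libraries that share the spread estimate, and the part played by library number was not tested. Lane 1 only, with fewer reads, gave 1 for the shRNA, 184, 20 and 0 for siRNA-2, the mean and the difference of effects. Each lane file as a library, which counts lanes as replicates and so understates the spread, gave 262, 5460, 5453, 4431, 7275 and 2619 for the 6 comparisons in order, and NNT with siRNA-2 passed (-1.10, adjusted p = 4.76e-08). DESeq2 gave 905, 859, 287 and 11 for siRNA-2, siRNA-3, the mean and the difference of effects. The estimated correlation gave 0 lists in all 5 list comparisons.

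Leaving out 1 library, counts ran from 1 (without NNT shRNA 18-3) to 2 (without scrambled shRNA 19-2) for the shRNA, from 2 (without scrambled siRNA 16-1) to 619 (without siRNA-2 11-12) for siRNA-2, from 69 (without siRNA-3 11-1) to 530 (without siRNA-3 30-11) for siRNA-3, from 2 (without scrambled siRNA 23-5) to 55 (without scrambled siRNA 30-11) for the mean, from 1091 (without siRNA-2 11-1) to 2101 between siRNAs and from 0 to 2 for the difference of effects. List counts ran from 0 to 9 for the shRNA, 4 to 7 for siRNA-2, 9 to 12 for siRNA-3, 4 to 8 for the mean and 2 to 7 for the difference. NNT ran from -3.65 to -3.45 with the shRNA, -1.51 to -0.68 with siRNA-2, -3.31 to -3.01 with siRNA-3 and -2.32 to -1.91 in the mean. The correlation ran from 0.196 to 0.393 between siRNAs and from 0.029 to 0.085 between shRNA and siRNAs. Over 71 named gene results in 1184 combinations with an alternative, 0 changed direction past the threshold, 116 lost their call, 37 gained one and 14 that did not pass changed sign.

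Counts of splits below include the real one. For genes, 1 of 35 splits of the shRNA libraries gave 3 or more (highest other 0), but the codes may pair these libraries, if weakly. Of the 8 splits that part all 3 pairs, too few for a share under 0.05, the real one alone gave as many (highest other 0). The other 27 gave 0. The 10 splits in each siRNA comparison are too few for a share under 0.05: siRNA-2 gave 299 (highest other 0) and siRNA-3 323 (highest other 75), and for lists 4 (7 splits as many, highest other 9) and 13 (1 split, highest other 8). For the mean, 7 of 100 splits, the real one among them and the others drawn, gave 35 or more, so chance is not excluded. The 95% exact binomial interval of that share, the real split counted, was 2.86 to 13.9%. The highest count, 1135, makes the siRNA-3 libraries the controls and so points to a structure of the samples. In each of the other drawn splits with 35 or more, siRNA-3 libraries also made up most or all of the controls. Such splits carry the difference between the siRNAs, so the share does not measure chance alone and cannot exclude it. For lists chance is not excluded for the shRNA (34 of 35 splits, real 1, highest other 16) or the mean (61 of 100, real 5, highest other 11). Depth limited CYP11B1, and 1.5-fold changes were often missed in simulation.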

Other observations

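The tests of MIR30A and its host gene were chosen only after the result was seen.

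Apart from the lists described, the siRNAs differed in genes of cell death and the p53 response, named here after their values were seen. With siRNA-2 relative to siRNA-3, 8 of 27 apoptosis genes were higher and 1 lower, the same when adjusted over the list alone. Those higher included PMAIP1 (log2 difference 1.86, SE 0.39) and BBC3 (1.77, SE 0.41), which promote cell death, and the death receptor FAS (0.90, SE 0.18). They also included BCL2L1 (0.47, SE 0.11), which counters cell death. PMAIP1 and BBC3 were low, at 3.1 and 3.85 CPM with siRNA-2 and 0.83 and 1.11 CPM with siRNA-3. Against the scrambled siRNA, FAS was 0.21 with siRNA-2 and -0.69 with siRNA-3. Of 24 p53 targets 5 were higher and 3 lower, the same when adjusted over the list alone; MDM2 (0.92, SE 0.15) and GADD45A (1.04, SE 0.26) were among those higher and TP53INP1 (-1.10, SE 0.17) and CCNG1 (-0.54, SE 0.12) among those lower. As lists neither passed camera (adjusted p = 0.26 and 0.394). Without the siRNA-2 library 11-1 PMAIP1 was 1.18 (adjusted p = 0.0291), and BBC3 (1.12, adjusted p = 0.0627) and GADD45A (0.56, adjusted p = 0.0884) missed the threshold, which GADD45A also missed without the siRNA-3 library 11-1 (adjusted p = 0.0554). Also named after their values were seen, SLC2A1, the main glucose transporter, was higher with siRNA-2 by 1.13 (SE 0.14), and DICER1 and AGO4, of the RNA interference machinery, were lower by -0.87 (SE 0.17) and -0.80 (SE 0.16).

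In NNT, 8-base words that join overlapping top 7-mers of each siRNA lie in the coding part of exon 21, CCTTGTAA at 43702634 to 43702641 and CAACTCTA at 43702685 to 43702692 of chromosome 5 (GRCh38), 1 site each. CAACTCTA joins the siRNA-3 7-mers ranked 2 and 3, and the leading CCAACTC overlaps it, at 43702684 to 43702690. The 8-base words were picked among candidates present in NNT, so their presence there is no evidence of itself. For the shRNA, the 7-mer most tied to lower levels had t = -4.6, against 4.6 as the largest absolute t in permutations; GATTACA, tied to higher levels, had t = 4.9. Those chosen for lower levels in one part of the genes had t of 0.2 and -1.9 in the other.

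Counts for MIR30A, a microRNA gene, were 86.8 to 155 CPM in the 7 shRNA libraries, NNT and scrambled alike, and 0 to 0.0993 CPM in the 9 siRNA libraries, with at least 2708 counts against at most 2. Transcription of the locus should raise its non-coding host gene LINC00472 too, but the ratio of mean CPM between shRNA and siRNA libraries was 0.814, which argues against it. Reads from an shRNA vector built on the miR-30 hairpin could give this, as a hypothesis that the counts alone cannot test; the vector is not given in the sources used here.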
